A study of Rattus norvegicus with 6 samples.

How the data were processed

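RNA from the lumbar spinal cord of 3 untreated and 3 lidocaine-treated Sprague-Dawley rats was measured on Affymetrix rat arrays from 150 ng of total RNA labelled with biotin, per the labels' protocols. Each array came from 1 rat. The groups and replicate numbers come from the sample titles. The labels give no batch.

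The values are log2 summary values per transcript cluster, deposited after RMA, per the submitters' processing notes. RMA corrects the background, makes the distributions of probe values equal across arrays and summarises the probes of a transcript cluster by median polish. The medians of the summary values can still differ between arrays. The software version, array model, genome build and annotation are not given in the sources used here. Equalised distributions remove differences in total signal, so a change is relative to the other genes of the same array, and a fold change taken from RMA values can understate the change of dim genes. The table held 65527 rows, of which 63789 were transcript clusters, 1153 negative controls, 399 positive controls, 155 ERCC spike-in controls and 31 other Affymetrix controls. The 95th percentile of the negative controls lay between 5.79 and 5.87 on the control arrays and between 5.99 and 6.06 on the lidocaine arrays. The median of the positive controls also differed by group, at 6.82 to 6.96 on the control arrays and 6.69 to 6.74 on the lidocaine arrays. The cause was not tested. The median of the negative controls lay between 2.65 and 2.81 on the 6 arrays. Antigenomic background rows lay between 0.60 and 5.77, so no single detection limit was set. Values of genes below the level of the brighter negative controls may lie near background. By a rule set after the values were seen, a named gene whose group mean lay below the mean over that group's arrays of the negative-control median is called at background there, and its fold is given against that median as a lower bound.

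Transcript clusters were named through the platform annotation. It gave exactly 1 gene for 21560 clusters, several genes for 471 and none for 41758. Clusters with several genes were not used for any gene. Symbols were brought up to date through gene identifiers in a RefSeq table of the rat assembly GRCr8, which held 20304 of the identifiers and changed 1 symbol. No coordinates were used, since the builds were not matched. Where several clusters named 1 gene, the brightest over all 6 arrays was kept, which set aside 1030 clusters and left 20530 genes. Near-identical gene copies can share probes, so values of such families are less certain.

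Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. An adjusted p is limma's unless another test is named. Fold changes are 2 to the power of the difference in mean log2 values. Standard errors are those of the moderated fit.

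Before the data were examined, 41 gene lists were fixed, for cell types of the cord, its roots, meninges and blood and for functions linked to injury, inflammation, excitability and metabolism. Of 571 members, 103 had no cluster naming that gene alone and were not analysed here. Older names matched 6 members. The 39 lists with at least 5 measured genes were tested with limma's camera, which asks whether the genes of a list move together relative to all other genes, with a preset correlation between genes of 0.01. With the correlation estimated from these 6 arrays, 4 of the 27 calls held, those of phagocytic microglia and macrophages, blood-derived monocytes and macrophages, reactive astrocyte genes and complement. A correlation estimated from so few arrays is itself imprecise. Of the 39 lists, fry, which asks only whether the genes of a list move one way on balance, called 22. Calls were also counted adjusted over the list alone. Y-linked genes were checked and did not set any sample apart: Kdm5d and Uty lay between 5.74 and 6.08 and Ddx3y and Eif2s3y between 7.04 and 7.72 on all 6 arrays, and Usp9y between 1.20 and 1.33.

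The genes named in the text follow a rule fixed at the same time: the 12 largest rises and 12 largest falls among genes past adjusted p 0.05 with no overlap between groups, leaving out unnamed loci and pseudogenes, up to 4 members with the smallest p from each list that passed or had at least 2 members called, and 17 genes of prior interest. Among the latter, Aif1, Mbp, Tnf and Mapk14 were not analysed here, and 1 other is not reported here. Not all genes that the rule takes but that did not pass are named. A gene outside the rule is marked as chosen after its value was seen.

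The steps were tested on simulated arrays with the real means and spreads of the 20530 genes, of which 200 were shifted. For this comparison, 56% of genes shifted by 0.5 on the log2 scale, 84% by 1, 100% by 2 and 98% by 3 were recovered. There were 10 calls among unshifted genes. With no shift, 0 lists were called. The shifted genes were not drawn from the genes with the lowest mean values, so recovery of dim genes was not tested. Each gene was simulated independently of the others. The list result therefore says nothing about calls among correlated genes.

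The alternatives planned in advance were a block for the replicate number, each rat left out in turn, quantile normalization of the transcript clusters, median centring of the arrays, leaving out the genes with the lowest mean values, the mean of a gene's clusters, array weights, a trended and robust variance, all transcript clusters in place of named genes, 3 other thresholds, and for the lists the estimated correlation, fry and camera on ranks.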

Results

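Gene expression was measured in the lumbar spinal cord of 6 Sprague-Dawley rats with 1 Affymetrix array per animal. Lidocaine, a local anaesthetic that blocks voltage-gated sodium channels, was given to 3 rats as 20 µL of a 10% solution into the intrathecal space, the fluid space around the cord. The other 3 rats were blank controls that were given no treatment. Cord from levels L2 to L6 was taken on day 4, after behavioural testing. The median log2 value over transcript clusters and control rows together lay between 3.07 and 3.20 on the 6 arrays. Over the named genes it was 4.56 to 4.59 on the control arrays and 4.61 to 4.66 on the lidocaine arrays. Values correlated at 0.994 to 0.996 between rats of the same group and at 0.987 to 0.992 between rats of different groups. These correlations were taken over all 63789 transcript clusters, named or not, which are not independent replicates. The number of arrays limits the precision.

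The comparison asks which genes differed in the cord 4 days after intrathecal lidocaine from the untreated cord. Genes of phagocytes, cytokines, complement, reactive astrocytes and dividing cells rose, and genes of neurons, neurotransmitter receptors, oligodendrocytes and cholesterol synthesis fell. As list shifts these held with an estimated correlation for phagocytes, complement and reactive astrocytes (adjusted p = 0.0473, 0.042 and 0.042 with an estimated correlation), and not for cytokines (0.15), cell cycle (0.228), neurons (0.377), glutamate receptors (0.27), GABA and glycine receptors (0.305), oligodendrocytes (0.179) or cholesterol synthesis (0.16). Of 20530 genes, 4867 changed (limma, adjusted p under 0.05, 3 rats per group). They comprised 1992 that rose, with a median log2 change of 0.51, and 2875 that fell, with a median of -0.39. Large changes were mostly rises: 365 genes rose and 9 fell by at least 2-fold, and 63 rose and 0 fell by at least 4-fold. In 8319 genes the 3 lidocaine values all lay on one side of the 3 control values, which is 40.5% of genes, against 10% by chance. Rises made up 40.9% of the calls, and 30.1% after median centring of the arrays. Without control rat 2, 2754 genes were called, 1412 higher and 1342 lower, and without control rat 3, 2906, 1299 higher and 1607 lower. In a principal component analysis 70.4% of the variance lay on the component that parted the groups and 12.7% on the next, on which lidocaine rat 3 stood apart, and without that rat 3893 genes were called. Since the controls were not injected, the effect of the drug and that of the injection itself are confounded.

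**Figure D1:**
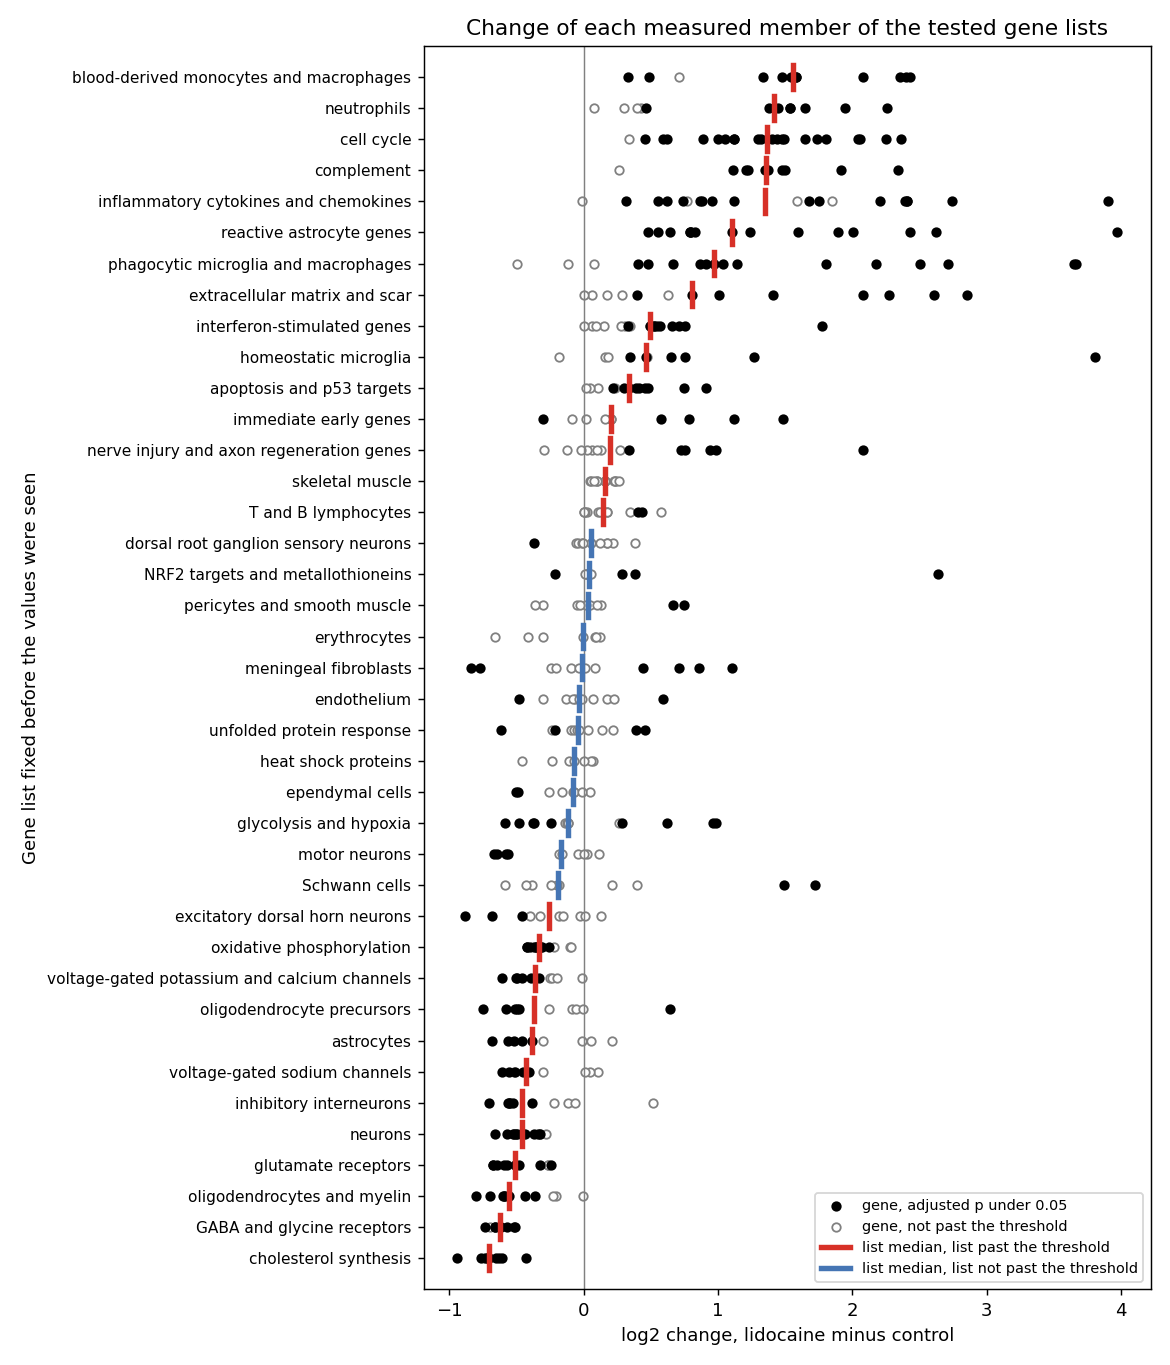
Log2 change between lidocaine and control (3 rats each) for every measured member of the 39 tested gene lists, 1 line per list, ordered by median. Filled points are genes past adjusted p 0.05, open points are not, and bars are list medians, in red for the 27 lists past the threshold with the preset correlation and in blue for the others; medians run from -0.71 for cholesterol synthesis to 1.56 for blood-derived monocytes and macrophages.

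The 12 largest rises included Serpina3n, a serine protease inhibitor made by reactive astrocytes, which rose 15.7-fold (log2 change 3.97 ± 0.70, SE, n = 3 per group, adjusted p = 0.00701). Its log2 change was 4.91 without lidocaine rat 3 and 1.99 as the mean of its clusters, which is below those of the other 11 genes. Ucn2, a peptide of the corticotropin-releasing factor family, rose 15.5-fold (log2 change 3.96 ± 0.25, SE, adjusted p = 0.00012). Ccl2, the chemokine that draws monocytes, rose 15-fold from 3.89 ± 0.26 to 7.80 ± 0.25 (SD, n = 3, adjusted p = 3.31e-05). Fcrl2, an Fc receptor-like gene, rose 14-fold, Lbp, which binds bacterial lipopolysaccharide, 13.2-fold, the fungal-glucan receptor Clec7a 12.7-fold and the glycoprotein gene Gpnmb 12.6-fold. The protease inhibitor Slpi rose 10.9-fold, but this call was lost without control rat 2 (adjusted p = 0.05004), and its log2 change of 3.44 was 2.75 without lidocaine rat 1 and 4.43 without lidocaine rat 3. Lilrb4, an inhibitory leukocyte receptor that was at background in the controls, rose at least 7.78-fold, the cytokine receptor chain Csf2rb 7.75-fold, Enpp3 7.39-fold and the matrix glycoprotein thrombospondin 1, Thbs1, 7.24-fold. Adjusted p of these 12 genes ran from 1.92e-05 for Clec7a to 0.0133 for Slpi.

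The 12 largest falls were smaller. Slc25a18, a mitochondrial glutamate carrier, fell by 1.28 on the log2 scale, 2.43-fold lower, from 7.22 ± 0.20 to 5.94 ± 0.24 (SD, n = 3 per group, adjusted p = 0.00114). B3galt2, a galactosyltransferase, was 2.2-fold lower, Capn6 2.17-fold, the heparan sulfate enzyme Ndst4 2.08-fold, the organic anion transporter Slc22a8 2.07-fold and the proteoglycan Spock3 2.01-fold lower. Elovl6, a fatty acid elongase, was 2.01-fold lower, Aldh1a1, which makes retinoic acid, 1.98-fold, the peroxisomal transporter Abcd2 1.97-fold and vitronectin, Vtn, 1.96-fold lower. Cnmd and Sfrp5 completed the 12, at 2.26-fold and 2.13-fold lower (adjusted p = 0.0235 and 0.0233). The call of Cnmd was lost without control rat 2 or 3 or lidocaine rat 1 or 2 (adjusted p 0.0621 to 0.0895), and that of Sfrp5 without control rat 2 or 3 or lidocaine rat 2 (adjusted p 0.0672 to 0.0733).

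Genes of microglia and macrophages rose. Among phagocytic microglia and macrophage genes, 14 of 17 rose, 0 fell and 3 did not pass, with 14 adjusted over the list alone. The galectin gene Lgals3 rose 6.57-fold (log2 change 2.71 ± 0.12, SE, n = 3 per group), and Tyrobp, the signalling adaptor of myeloid receptors, rose 3.5-fold. The list shifted up (median log2 change 0.97, limma's camera test, adjusted p = 1.09e-11), also with an estimated correlation (adjusted p = 0.0473). Of the blood-derived monocyte and macrophage genes, 11 of 12 rose and 1 did not pass, with 12 adjusted over the list alone. They included the scavenger receptor Msr1 at 5.39-fold, the lysozyme gene Lyz2 at 2.92-fold and the mannose receptor Mrc1 at 2.52-fold (adjusted p = 0.000125, 3.56e-05 and 0.000304). That list shifted up with the preset and with an estimated correlation (median 1.56, adjusted p = 8.75e-12 and 0.042). Ccr2 and Cd14, also fixed for this list, were not analysed here. Whether the rise came from blood-derived cells was not tested. Of the homeostatic microglia genes, 6 of 10 rose and 4 did not pass, and 7 changed adjusted over the list alone, 6 up and 1 down. Csf1r, the receptor on which microglia depend, rose 2.4-fold (log2 change 1.27 ± 0.077, SE), the fractalkine receptor Cx3cr1 1.69-fold and P2ry13 1.27-fold. Tmem119 and Selplg, chosen after their values were seen, had log2 changes of 0.16 and -0.18 and did not pass (adjusted p = 0.419 and 0.0672). The homeostatic list shifted up with the preset correlation (adjusted p = 5.38e-05) but not with the estimated one (adjusted p = 0.179 with an estimated correlation). Aif1, another microglial marker, was not analysed here.

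Among neutrophil genes 8 of 12 rose and 4 did not pass, with 8 adjusted over the list alone. The calcium-binding protein genes S100a9 and S100a8 rose 4.79-fold and 2.73-fold, the collagenase Mmp8 3.86-fold and the granulocyte growth factor receptor Csf3r 3.14-fold (n = 3 per group, adjusted p 0.000304 to 0.000791). The neutrophil list shifted up (median 1.41, adjusted p = 4.01e-07), which was lost with the estimated value (adjusted p = 0.16 with an estimated correlation). Of 12 T and B lymphocyte genes, 2 rose, 10 did not pass, and 2 passed adjusted over the list alone. The T cell surface genes Cd2, at background in the controls, and Cd8a rose at least 1.27-fold and 1.35-fold (adjusted p = 0.0097 and 0.0121). The small shift of the lymphocyte list (median 0.15, adjusted p = 0.0191) was lost without lidocaine rat 3 (adjusted p = 0.0525), with dim genes left out (0.0684), with fry (0.117) and at adjusted p = 0.469 with an estimated correlation.

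Cytokine and chemokine genes rose in 16 of 20 cases, with 4 not past the threshold and 19 past it adjusted over the list alone. Il6, at background in the controls, rose at least 2.68-fold to 4.13 ± 1.07 (log2, SD, n = 3, adjusted p = 0.0114), and Ptgs2, the inducible cyclooxygenase, rose 5.32-fold. The inflammasome gene Nlrp3 rose 1.94-fold and the receptor gene Tlr2 1.83-fold. Il1b rose 6.68-fold (adjusted p = 0.0137), but its 3 lidocaine values of 7.17, 6.40 and 4.44 were far apart, and the call was lost without control rat 2 (adjusted p = 0.0536). The log2 change of Il1b, 2.74, was 2.15 without lidocaine rat 1 and 3.52 without lidocaine rat 3. Tnf was not analysed here. The list shifted up (median 1.35, adjusted p = 8.75e-12), though not with an estimated correlation, where adjusted p = 0.15 with an estimated correlation. In lidocaine rat 3 its mean was 1.05 above the controls on the log2 scale, against 1.89 and 1.53 in lidocaine rats 1 and 2.

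Complement genes rose in 9 of 10 cases, with 1 not past the threshold and 10 past it adjusted over the list alone. The subunits of C1q, the first component of the classical pathway, rose 5.07-fold for C1qb, 2.78-fold for C1qa and 2.33-fold for C1qc (adjusted p = 2.6e-05, 0.000273 and 0.00042, n = 3 per group), and the receptor C5ar1 3.77-fold. The complement list shifted up with the preset and with an estimated correlation (median 1.36, adjusted p = 1.12e-10 and 0.042). Of the interferon-stimulated genes 10 of 18 rose and 8 did not pass, with 12 adjusted over the list alone. Gbp2, a guanylate-binding protein, rose 3.42-fold, and the transcription factors Irf1 and Irf9 1.58-fold and 1.41-fold, and Oas1a 1.44-fold. That list shifted up (median 0.49, adjusted p = 2.16e-06), a call lost at adjusted p = 0.27 with an estimated correlation. MHC class I was represented by 1 measured gene, B2m, which rose (log2 change 0.30, adjusted p = 0.0156). MHC class II had 3 measured genes, of which Ctss, a lysosomal protease, rose (log2 change 0.61, adjusted p = 0.00817), while Ciita and Cd74 did not pass (log2 changes 0.12 and 0.10). The counts adjusted over the list alone were also 1 of 1 and 1 of 3. Neither MHC list had the 5 measured genes needed for a test, and B2m, Ctss, Ciita and Cd74 were chosen after their values were seen.

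Reactive astrocyte genes rose, and some general astrocyte markers fell. All 15 measured reactive astrocyte genes rose, both over all genes and adjusted over the list alone (15). Gfap, the intermediate filament of astrocytes, rose 1.74-fold from 9.05 ± 0.10 to 9.84 ± 0.22 (log2, SD, n = 3 per group, adjusted p = 0.0033). Timp1, an inhibitor of matrix proteases, rose 6.15-fold, the oncostatin M receptor Osmr 5.39-fold, ceruloplasmin, Cp, 3.71-fold and the adhesion receptor Cd44 3.03-fold. The list shifted up with the preset and with an estimated correlation (median 1.10, adjusted p = 1.1e-13 and 0.042). Of 9 astrocyte markers, 5 fell, 0 rose and 4 did not pass, and 7 passed adjusted over the list alone, 6 lower and 1 higher. Aldh1l1, a folate enzyme of astrocytes, was 1.48-fold lower and the bicarbonate transporter Slc4a4 1.43-fold lower (adjusted p = 0.000994 and 0.00241). Gjb6 fell (log2 change -0.68, adjusted p = 0.0181), a call lost without control rat 1 or 2 (adjusted p 0.0563 to 0.0575), and Aldoc fell (log2 change -0.46, adjusted p = 0.0281), a call lost without any 1 control rat (adjusted p 0.0655 to 0.0965). The astrocyte list shifted down (median -0.38, adjusted p = 0.0252), but not without control rat 2 (adjusted p = 0.0537), with dim genes left out (0.111) and at adjusted p = 0.469 with an estimated correlation.

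Cell cycle genes rose in 21 of 22 cases, with 1 not past the threshold and 22 past it adjusted over the list alone. Mki67, a marker of dividing cells, rose 5.15-fold from 4.74 ± 0.16 to 7.11 ± 0.42 (log2, SD, n = 3 per group, adjusted p = 0.000338). Topoisomerase 2-alpha, Top2a, rose 4.76-fold, the mitotic kinase Aurkb 2.79-fold and survivin, Birc5, 2.17-fold. The list had the smallest p of all 39 with the preset correlation (median 1.36, adjusted p = 3.93e-19), and adjusted p = 0.228 with an estimated correlation. Extracellular matrix and scar genes rose in 8 of 13 cases, 5 did not pass, and 9 passed adjusted over the list alone. Periostin, Postn, rose 6.09-fold, fibronectin, Fn1, 4.23-fold and neurocan, Ncan, 1.75-fold (adjusted p = 0.000424, 0.000424 and 0.000573). Versican, Vcan, a member of the blood-derived monocyte and macrophage list and not of this one, rose 2.99-fold. Fn1 is a member of both lists. The matrix list shifted up (median 0.81, adjusted p = 2.16e-07), with adjusted p = 0.205 with an estimated correlation.

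Of 13 apoptosis and p53 target genes 9 rose and 4 did not pass, with 9 adjusted over the list alone. The rises were modest, with Pmaip1 (also called Noxa) 1.88-fold higher, the initiator caspase Casp8 1.68-fold, the death receptor Fas 1.4-fold and Ccng1 1.31-fold higher (adjusted p 0.00041 to 0.00467, n = 3 per group). Bax and Bcl2, which promote and oppose cell death, had log2 changes of 0.11 ± 0.067 and 0.018 ± 0.076 (SE) and did not pass (adjusted p = 0.293 and 0.895). Mapk14 was not analysed here. The list shifted up (median 0.34, adjusted p = 3.52e-06), with adjusted p = 0.16 with an estimated correlation. Among nerve injury and axon regeneration genes 6 of 14 rose and 8 did not pass, with 6 adjusted over the list alone. Annexin A1, Anxa1, rose 4.24-fold, Gadd45a 1.98-fold, the injury transcription factor Atf3 1.92-fold (log2 change 0.94 ± 0.15, SE, adjusted p = 0.00562) and Sprr1a, at background in the controls, at least 1.16-fold. That list shifted up (median 0.20, adjusted p = 0.00101), with adjusted p = 0.27 with an estimated correlation. Of 10 immediate early genes 4 rose, 1 fell and 5 did not pass, with 6 adjusted over the list alone. Fos rose 2.79-fold and Fosl1 2.18-fold (adjusted p = 0.000681 and 0.00163), while Arc, a gene of synaptic plasticity, was 1.23-fold lower, a call lost without control rat 2 (adjusted p = 0.0501). Egr1 rose (log2 change 0.58, adjusted p = 0.0301), a call lost without control rat 1 or 3 or lidocaine rat 2 or 3 (adjusted p 0.0756 to 0.105). The immediate early list shifted up (median 0.21, adjusted p = 0.0158), with adjusted p = 0.27 with an estimated correlation.

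**Figure D2:**
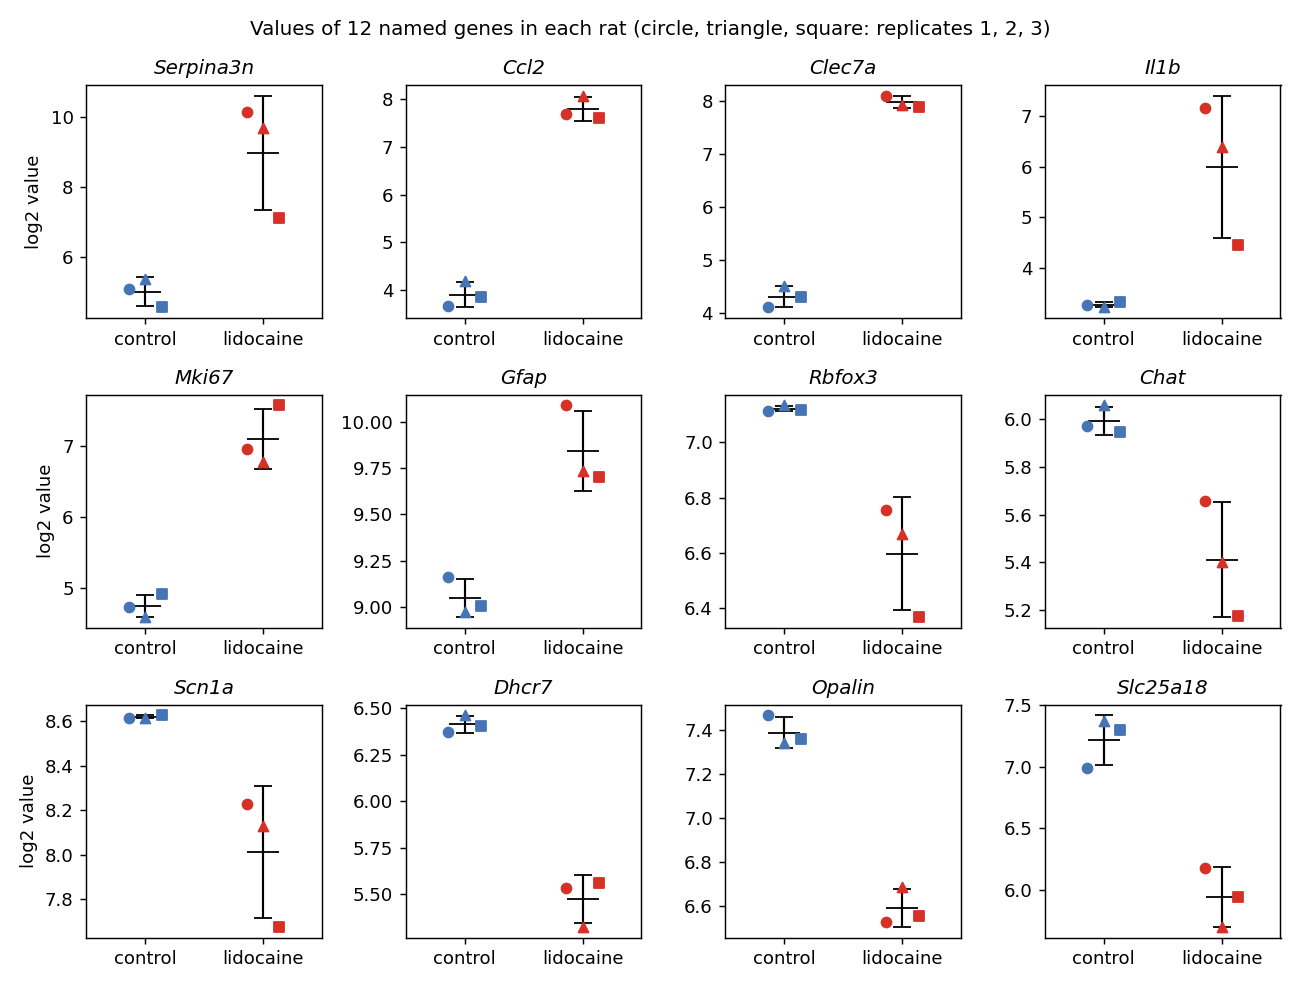
Log2 values of 12 named genes in each rat, with controls in blue and lidocaine in red, a circle, triangle and square for replicates 1, 2 and 3, and bars for the group mean ± SD (n = 3); each panel has its own y axis. Serpina3n and Il1b were lowest in lidocaine rat 3 among the lidocaine rats, at 7.11 and 4.44. All 12 genes shown had passed adjusted p 0.05, and none overlapped between groups. This follows from the choice, since 4858 of all 4867 genes that passed had no overlap.

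Neuronal genes fell. Of 14 general neuron markers 12 fell, 2 did not pass and 0 rose, with 14 lower adjusted over the list alone. Rbfox3, which encodes the nuclear marker NeuN, fell from 7.12 ± 0.01 to 6.60 ± 0.20 on the log2 scale, 1.44-fold lower (SD, n = 3 per group, adjusted p = 0.0095). The RNA-binding protein gene Elavl4 was 1.58-fold lower, the synaptic vesicle gene Syn1 1.41-fold and the synaptic fusion gene Snap25 1.37-fold lower. The neuron list shifted down (median -0.46, adjusted p = 1.93e-06), with adjusted p = 0.377 with an estimated correlation. Among 10 motor neuron markers 4 fell and 6 did not pass, and 5 passed adjusted over the list alone. Chat, the enzyme that makes acetylcholine, was 1.49-fold lower (log2 change -0.58 ± 0.12, SE, adjusted p = 0.0112) and the choline transporter Slc5a7 1.57-fold lower. Slc18a3 fell (log2 change -0.56, adjusted p = 0.0306), a call lost without control rat 2 or 3 or lidocaine rat 2 or 3 (adjusted p 0.0792 to 0.111), and Chodl fell (log2 change -0.67, adjusted p = 0.0321), a call lost without any 1 control rat or lidocaine rat 2 or 3 (adjusted p 0.0721 to 0.108). The shift of the motor neuron list did not pass (median -0.17, adjusted p = 0.0552, and 0.469 with an estimated correlation), but did without control rat 1, lidocaine rat 1 or lidocaine rat 2 (adjusted p = 0.0462, 0.0121 and 0.0446) and with array weights (0.0461). Of 10 inhibitory interneuron genes 6 fell and 4 did not pass, and adjusted over the list alone 7 were lower and 1 higher. Pax2, a transcription factor of these cells, was 1.3-fold lower, and the vesicular transporter of GABA and glycine, Slc32a1, was 1.48-fold lower, a call lost without control rat 2 (adjusted p = 0.0521). Slc6a5 fell (log2 change -0.70, adjusted p = 0.0255), a call lost without any 1 control rat (adjusted p 0.0663 to 0.0843), and Gad2 fell (log2 change -0.55, adjusted p = 0.0259), a call lost without control rat 1 or 2 (adjusted p 0.0581 to 0.0918). The inhibitory list shifted down (median -0.45, adjusted p = 0.0108), a call lost with dim genes left out (adjusted p = 0.0604), with fry (0.0701) and at adjusted p = 0.469 with an estimated correlation. Its mean change was -0.32, and -0.20 without lidocaine rat 3. Of 10 excitatory dorsal horn genes 3 fell and 7 did not pass, with 5 adjusted over the list alone. The neuropeptide gene Sst was 1.85-fold lower (adjusted p = 0.0138). Slc17a6 fell (log2 change -0.68, adjusted p = 0.0218), a call lost without control rat 1 or 2 (adjusted p 0.0648 to 0.0807), and Tac3 fell (log2 change -0.46, adjusted p = 0.032), a call lost without control rat 2 or 3 or lidocaine rat 1 or 3 (adjusted p 0.0533 to 0.0878). The shift of the dorsal horn list (median -0.25, adjusted p = 0.0479) was lost without control rat 1 or 2 or lidocaine rat 1 or 3 (adjusted p 0.0671 to 0.086), after quantile normalization (0.063) or median centring (0.068), with dim genes left out (0.173), array weights (0.147) or fry (0.14), and at adjusted p = 0.512 with an estimated correlation.

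Genes of ion channels and transmitter receptors also fell. The list test compares them with all other genes, not with neuron genes, whose list median was -0.46. A lower share of neuronal RNA and a change specific to channels or receptors therefore cannot be told apart here. Of 10 voltage-gated sodium channel genes, the targets of lidocaine, 5 fell and 5 did not pass, with 6 adjusted over the list alone. Scn2a was 1.42-fold lower (log2 change -0.51 ± 0.11, SE, n = 3 per group, adjusted p = 0.0126) and the beta subunit Scn2b 1.37-fold lower. Scn1a and Scn8a were 1.53-fold and 1.47-fold lower (adjusted p = 0.0152 and 0.0157), calls that were lost without control rat 2 (adjusted p = 0.0548 and 0.0552) or control rat 3 (adjusted p = 0.0523 and 0.0607). Scn9a, a channel of sensory neurons, had a log2 change of 0.11 ± 0.10 and did not pass (adjusted p = 0.513). The sodium channel list shifted down (median -0.43, adjusted p = 0.0252), but not without control rat 2 (adjusted p = 0.059), after median centring (0.0537), with dim genes left out (0.113) and at adjusted p = 0.433 with an estimated correlation. Of 11 potassium and calcium channel genes 7 fell and 4 did not pass, with 8 adjusted over the list alone. Kcnc1, a channel of fast-spiking neurons, was 1.52-fold lower, a call lost without control rat 2 (adjusted p = 0.0553). Cacna1g fell (log2 change -0.39, adjusted p = 0.0167), a call lost without control rat 2 or 3 (adjusted p 0.0631 to 0.0639), Kcna2 fell (log2 change -0.46, adjusted p = 0.0168), a call lost without control rat 2 or 3 (adjusted p 0.0621 to 0.066), and Cacna1e fell (log2 change -0.50, adjusted p = 0.0177), a call lost without control rat 2 or 3 or lidocaine rat 2 (adjusted p 0.0511 to 0.0679). The channel list shifted down (median -0.36, adjusted p = 0.000519, but 0.0506 with fry and adjusted p = 0.433 with an estimated correlation). Glutamate receptor genes fell in 9 of 11 cases, 2 did not pass, and 11 passed adjusted over the list alone. The NMDA receptor genes Grin2a and Grin2b were 1.59-fold and 1.5-fold lower and the AMPA receptor gene Gria3 1.59-fold lower (adjusted p = 0.00757, 0.00424 and 0.00637), and the metabotropic receptor gene Grm3 1.57-fold lower. That list shifted down (median -0.51, adjusted p = 7.64e-06), with adjusted p = 0.27 with an estimated correlation. GABA and glycine receptor genes fell in 9 of 10 cases, 1 did not pass, and 10 passed adjusted over the list alone. Gabra2 was 1.42-fold lower, Gabrb1 1.58-fold and the glycine receptor gene Glra3 1.54-fold lower, as was the GABA-B receptor gene Gabbr2, 1.54-fold, a call lost with the mean of its clusters (adjusted p = 0.057). The inhibitory receptor list shifted down (median -0.62, adjusted p = 8.34e-06), with adjusted p = 0.305 with an estimated correlation.

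Genes of oligodendrocytes, cholesterol synthesis and oxidative phosphorylation fell. Of 11 oligodendrocyte and myelin genes 8 fell and 3 did not pass, with 8 adjusted over the list alone. Opalin, a membrane protein of myelinating cells, was 1.74-fold lower (log2 change -0.80 ± 0.071, SE, n = 3 per group, adjusted p = 0.000468), Ugt8, which makes the myelin lipid galactocerebroside, 1.62-fold, Cnp 1.51-fold and Mal 1.51-fold lower. Mbp was not analysed here. The myelin list shifted down (median -0.56, adjusted p = 8.34e-06), with adjusted p = 0.179 with an estimated correlation. Among 10 oligodendrocyte precursor genes 5 fell, 1 rose and 4 did not pass, with 6 adjusted over the list alone. The growth factor receptor Pdgfra rose 1.56-fold (adjusted p = 0.00222), while brevican, Bcan, was 1.68-fold lower and the transcription factor Olig1 1.4-fold lower (adjusted p = 0.00337 and 0.00696), and the matrix glycoprotein gene Tnr 1.43-fold lower. The precursor list shifted down (median -0.37, adjusted p = 0.034), but not without lidocaine rat 2 (adjusted p = 0.0697), after quantile normalization (0.0663) or median centring (0.068), with dim genes left out (0.133) and at adjusted p = 0.228 with an estimated correlation. All 10 measured cholesterol synthesis genes fell, both over all genes and adjusted over the list alone (10). Dhcr7, the last enzyme of one branch of the pathway, was 1.92-fold lower, from 6.41 ± 0.046 to 5.47 ± 0.13 (log2, SD, n = 3 per group, adjusted p = 0.000388). Idi1, Cyp51 and Msmo1 were 1.7-fold, 1.64-fold and 1.53-fold lower. The cholesterol list shifted down (median -0.71, adjusted p = 4.49e-09), with adjusted p = 0.16 with an estimated correlation. Of 16 oxidative phosphorylation genes 11 fell and 5 did not pass, with 13 adjusted over the list alone. Sdha was 1.34-fold lower and Uqcrc1 1.27-fold lower. Ndufs3 fell (log2 change -0.40, adjusted p = 0.0136), a call lost without control rat 2 (adjusted p = 0.0504), and Ndufs1 fell (log2 change -0.42, adjusted p = 0.0153), a call lost without control rat 2 (adjusted p = 0.0587). The list shifted down (median -0.33, adjusted p = 8.34e-06, and adjusted p = 0.433 with an estimated correlation). Glycolysis and hypoxia genes went both ways, with 4 higher, 5 lower and 5 of 14 not past the threshold, and 9 past it adjusted over the list alone. Hk2 and Ldha rose 1.98-fold and 1.95-fold, and Vegfa and Pfkp were 1.29-fold and 1.39-fold lower (adjusted p = 0.000627, 0.000603, 0.00757 and 0.00856). The glycolysis list was not called (adjusted p = 0.773, direction down), and its median of -0.12 and mean of 0.041 differed in sign.

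Vascular, root, meningeal and ependymal genes showed no list shift past the threshold. Of 11 endothelial genes 1 rose, 1 fell and 9 did not pass, with 2 adjusted over the list alone. Vwf, the clotting glycoprotein, rose 1.5-fold (adjusted p = 0.00818, n = 3 per group), and the lipid transporter Mfsd2a of the blood-brain barrier was 1.39-fold lower, a call lost without any 1 rat other than lidocaine rat 1 (adjusted p 0.0586 to 0.0734). The endothelial list had adjusted p = 0.826, with median -0.036 and mean -0.0041 below 0 while the test pointed up. Of 10 pericyte and smooth muscle genes 2 rose and 8 did not pass, with 2 adjusted over the list alone. Tagln, a gene of contractile cells, rose 1.59-fold (adjusted p = 0.00859), and Des rose (log2 change 0.75, adjusted p = 0.0283), a call lost without any 1 control rat or lidocaine rat 1 or 3 (adjusted p 0.0505 to 0.0778). The pericyte list had median 0.034 and adjusted p = 0.484, and passed, upward, without lidocaine rat 2 (adjusted p = 0.0264). Of 10 Schwann cell genes 2 rose and 8 did not pass, with 2 adjusted over the list alone. Gldn, a gene of the node of Ranvier, rose 3.3-fold (adjusted p = 0.00229), and the neurotrophin receptor Ngfr rose 2.82-fold, a call lost without any 1 control rat or lidocaine rat 2 (adjusted p 0.088 to 0.119) and with a trended and robust variance (0.0657). The Schwann cell list had adjusted p = 0.773, pointing up, with a median of -0.19 and a mean of 0.18, which differ in sign. Meningeal fibroblast genes comprised 4 that rose, 2 that fell and 6 of 12 that did not pass, with 6 adjusted over the list alone. Dcn and Aldh1a2 rose 1.64-fold and 1.81-fold, and Ptgds and Igf2 were 1.79-fold and 1.71-fold lower (adjusted p 0.00337 to 0.00677). The meningeal list had adjusted p = 0.584, pointing up, with a median of -0.0081 below 0 and a mean of 0.086 above it. Of 9 ependymal genes 2 fell and 7 did not pass, with 2 adjusted over the list alone. The ciliary motor gene Dnah5 was 1.41-fold lower (adjusted p = 0.00723), and Tmem212 fell (log2 change -0.50, adjusted p = 0.0319), a call lost without control rat 3 or any 1 lidocaine rat (adjusted p 0.0508 to 0.0823). The ependymal list had median -0.079 and adjusted p = 0.124. Of 11 dorsal root ganglion genes 1 fell, Calcb, chosen after its value was seen (log2 change -0.37, adjusted p = 0.00847), and 10 did not pass. The ganglion list had 1 call adjusted over the list alone, median 0.053 and adjusted p = 0.616.

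Erythrocyte and muscle genes were measured as signs of blood and of tissue around the cord. None of the 7 erythrocyte genes passed over all genes (0 up, 0 down) or adjusted over the list alone (0). The erythrocyte list had median -0.0026 and adjusted p = 0.773, and passed, downward, without lidocaine rat 3 (adjusted p = 0.0127). None of the 11 skeletal muscle genes passed, with 0 adjusted over the list alone, and Tnnt3 and Mb had log2 changes of 0.23 and 0.24 (adjusted p = 0.0788 and 0.0799), though Tnnt3 passed with array weights (0.0436). Yet the muscle list as a whole shifted up (median 0.16, adjusted p = 0.0191), which was lost without control rat 2 (adjusted p = 0.0791) or lidocaine rat 3 (adjusted p = 0.107), after quantile normalization (0.0519), with dim genes left out (0.0505), with fry (0.24) and at adjusted p = 0.552 with an estimated correlation. Relative to lidocaine rats 1 and 2, lidocaine rat 3 was higher in erythrocyte genes by 0.72 ± 0.11, in Schwann cell genes by 0.62 ± 0.14, in meningeal genes by 0.48 ± 0.12 and in cell cycle genes by 0.54 ± 0.057 on the log2 scale (mean ± SE over genes). It was lower in neuron genes, with a difference of -0.32 ± 0.021. Genes are not independent, and these standard errors do not measure the spread between rats.

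**Figure D3:**
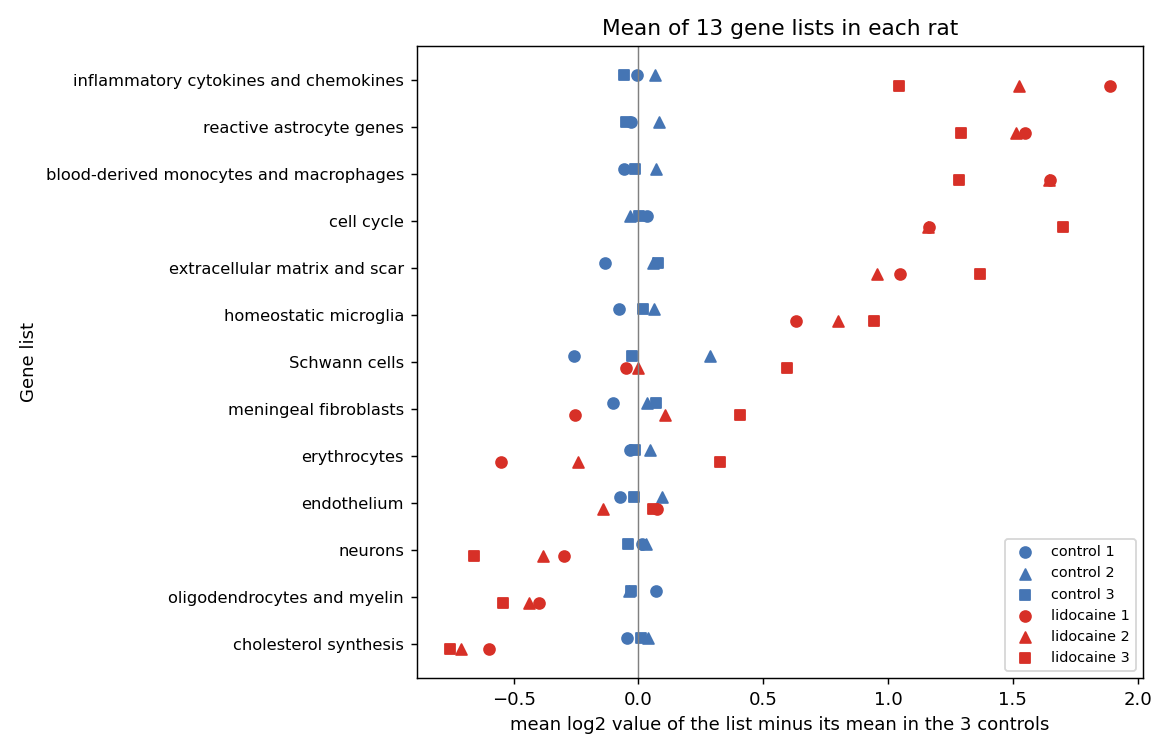
Mean log2 value of 13 gene lists in each rat, relative to the mean of the 3 controls, with controls in blue, lidocaine in red, and a circle, triangle and square for replicates 1, 2 and 3. Neuron genes lay at -0.30, -0.38 and -0.66 and cell cycle genes at 1.17, 1.16 and 1.70 in lidocaine rats 1, 2 and 3.

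The stress lists that remained were not called. Of 12 unfolded protein response genes 2 rose, 2 fell and 8 did not pass, with 4 adjusted over the list alone. Xbp1, a transcription factor of this response, and the chaperone Pdia4 rose 1.37-fold and 1.31-fold (adjusted p = 0.00591 and 0.00432, n = 3 per group). Chac1 fell (log2 change -0.61, adjusted p = 0.0291), a call lost without any 1 control rat or lidocaine rat 2 (adjusted p 0.071 to 0.0919), and Ddit3 fell (log2 change -0.21, adjusted p = 0.0314), a call lost without any 1 rat (adjusted p 0.0604 to 0.11). That list had adjusted p = 0.773, pointing up, although its median of -0.042 and mean of -0.0052 lay below 0. Of 9 NRF2 target and metallothionein genes 3 rose, 1 fell and 5 did not pass, with 4 adjusted over the list alone. The metal-binding protein gene Mt1 rose 6.23-fold (log2 change 2.64 ± 0.29, SE, adjusted p = 0.00118) and Nfe2l2 itself, the gene of NRF2, 1.3-fold (adjusted p = 0.00497). Gclm fell (log2 change -0.21, adjusted p = 0.0319), a call lost without any 1 rat (adjusted p 0.0514 to 0.0999), and Txnrd1 rose (log2 change 0.29, adjusted p = 0.0402), a call lost without any 1 control rat or lidocaine rat 1 or 2 (adjusted p 0.0727 to 0.123), the latter also after median centring (0.066). The list had median 0.037 and adjusted p = 0.108, and passed, upward, without lidocaine rat 3 (adjusted p = 0.0182) and with array weights (0.0461). None of the 7 heat shock genes passed, with 0 adjusted over the list alone, median -0.074 and adjusted p = 0.6.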

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

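No test of this part was chosen after its result was seen. Transcript clusters with no gene name were not used in the comparison, and 1757 of the 41758 passed the threshold in a fit of all transcript clusters. Of these 1113 were higher and 644 lower in lidocaine than in control rats. That is 4.21% of the unnamed clusters, against 14.6% of the named ones in the same fit. The largest rise among them was 3.27 and the largest fall -1.60 on the log2 scale. In a limma fit of all rows, 1 of 155 spike-in controls passed, with 10 at an unadjusted p under 0.05, and 0 of the 31 other Affymetrix controls, with 1 at an unadjusted p under 0.05.

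The real grouping called 4867 genes, the other 9 ways of splitting the 6 arrays into 3 and 3 called at most 0, and 1 of the 10 splits, the real one, reached the real count. With only 10 splits a share under 0.05 cannot be reached.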

How the results depend on the processing

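All alternatives were planned. No call of a list or named gene reversed direction under any alternative. Over the 6 fits that left out 1 rat, the genes changed ran from 2754 to 4335, those higher from 1299 to 1912 and those lower from 1342 to 2423; with fewer arrays the tests have less power. With at least 2-fold change required, 374 genes passed, 365 higher and 9 lower. At unadjusted p under 0.05 with at least 1.5-fold change there were 1244, 846 higher and 398 lower. Both follow from the thresholds themselves. The other alternatives gave 4005 to 6319 genes. Median centring removes the higher medians of the named genes on the lidocaine arrays. It moved the median log2 change of all genes from -0.0095 to -0.057. Median centring gave 5847 calls, with 4636 of the original 4867 kept. The share of rises among calls was 30.1% there, 38.5% after quantile normalization, 52.8% over all transcript clusters and 51.3% without control rat 2, against 40.9%.

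The labels do not say that same-numbered rats were paired. Deviations of same-numbered rats from their group means correlated at -0.063, -0.24 and 0.14 over genes. Those of differently numbered rats correlated at -0.22 to 0.38. So few correlations cannot decide whether the rats were paired. With the replicate block 4005 genes were called, 1737 higher and 2268 lower. It called 28 lists, the motor neuron list being added (camera adjusted p = 0.0479) and none lost. Of the named genes 4 lost their call with the block: Slc18a3, Txnrd1, Gclm and Ddit3 (limma adjusted p 0.0616 to 0.0959).

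The lists shifted numbered 4 with an estimated correlation, and 20 to 28 under the other alternatives, including 23 to 28 with 1 rat left out. Of the 27 calls, 4 held in all 15 settings, 15 were lost only with the estimated correlation and 8 in other settings too, 7 of them with dim genes left out. Of the 151 named genes that passed, 119 kept their call in every setting, and losses without 1 rat ran from 7 to 29 genes. Of genes whose signal lies near the background, little can be said. The cause of other differences between settings was not tested.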

Other observations

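The 4 gene groups of this paragraph and the genes named from them were chosen after the values were seen, so their tests, adjusted over these 4 groups only, are descriptive. Fatty acid synthesis and elongation genes fell with cholesterol synthesis: 12 of 15 fell and 0 rose, among them the desaturase Scd (log2 change -0.93 ± 0.10, SE, n = 3 per group, limma adjusted p = 0.000959), the synthase Fasn (-0.62 ± 0.068) and Acss2 (-0.84 ± 0.10). The group's median change was -0.43 (camera adjusted p = 2.69e-08, and 0.0156 with an estimated correlation). All 13 Fc receptor and C-type lectin genes rose, with a median of 1.82, including the inhibitory receptor Fcgr2b (2.80 ± 0.19) and Clec12a (2.08 ± 0.17), and the shift had adjusted p = 9.4e-15, and 0.0339 with an estimated correlation. Ribosomal protein genes rose in 12 of 14 cases (median 0.42), such as Rps18 (0.85 ± 0.12) and Rplp0 (0.67 ± 0.083), with adjusted p = 1.64e-09, and 0.0917 with an estimated correlation. Lysosomal genes rose in 8 of 14 cases (median 0.39), led by the cathepsins Ctsz (1.98 ± 0.092) and Ctsc (1.92 ± 0.15), while the membrane protein gene Lamp1 did not pass (-0.0063 ± 0.066), and the shift had adjusted p = 1.16e-06, and 0.0495 with an estimated correlation.

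Lidocaine rat 3 also had the highest value of all 6 rats for 8 of 9 granulocyte precursor genes, with the granule gene Ngp at 6.90 against 4.04 to 5.36 in the other 5 rats, for 4 of 10 genes of bone-forming cells and for 4 of 6 erythroid precursor genes. These 4 erythroid genes are members of the erythrocyte list too, and 4 of the 8 granulocyte genes of the neutrophil list, so these counts are in part the same values. The granulocyte list was chosen after the values were seen. The bone-forming list was written before its values were examined, as a test for bone and marrow tissue in that sample, and left this undecided (exact two-sided binomial p = 0.0697 against 1 in 6 by chance). The binomial test takes genes of 1 sample as independent, which they are not.

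Of the tests in the next paragraphs, those against vascular genes, against oligodendrocyte and astrocyte genes and between lidocaine rats were chosen after the result was seen. Neuronal genes were lower in all 3 lidocaine rats. If RNA from cells that joined or multiplied had diluted all resident cells alike, vascular genes would be lower by as much. But neuron genes changed by -0.45 ± 0.11 (mean ± SD over 14 genes) and endothelial and pericyte genes by 0.044 ± 0.32 (21 genes). The two-sided permutation p was 1e-05 over genes, the smallest that 100000 permutations can give. Genes are not independent, and rats were not permuted. A trend with brightness left by normalization is also unlikely as the only cause. The median of -0.46 lay at percentile 0.07 of 10000 random lists matched on mean value. Of the matched medians 2.5% lay below -0.33 and as many above 0.072. That range reached further down than up, so such a trend may account for part of the fall. But the matched lists were drawn from all genes, among them genes that fell. The range alone therefore does not show such a trend. Oligodendrocyte genes changed by as much (-0.46 ± 0.24), so a dilution in which vascular cells multiplied too stays open, as do a loss of neurons and lower transcription in living ones, all untested.

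Cytokine genes were lower in lidocaine rat 3 than in the other lidocaine rats, with a difference of -0.66 ± 0.22 on average (log2, SE over 20 genes), and 13 of 20 lay below both. The standard errors of this paragraph are over genes, which are not independent, and do not measure the spread between rats. A compressed signal on that array would bring all raised lists closer to the controls, but cell cycle genes were 0.54 ± 0.057 higher there. A cord less affected by the injection would by itself have neuron genes closer to the controls, but they lay further away, with a difference of -0.32 ± 0.021. This cannot exclude a less affected cord, since more root and meningeal tissue in that sample could also lower neuron genes. A response that was further along in time in that rat, or a different mix of root and meningeal tissue, may account for the lower cytokine genes. Neither was tested. The Schwann cell genes, higher there by 0.62, go with the latter. But the Schwann cell list also varied among control rats 1, 2 and 3, at -0.26, 0.29 and -0.028. Their cytokine means differed little, at -0.0064, 0.065 and -0.059.

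Cholesterol synthesis genes fell more than oligodendrocyte genes (-0.69 ± 0.13 against -0.46 ± 0.24, mean ± SD over 10 and 11 genes, two-sided permutation p = 0.0128 over genes, which are not independent). They also fell more than astrocyte genes (-0.29 ± 0.31, 9 genes, two-sided exact permutation p = 0.000628). A lower share of either cell type alone would lower both lists alike if every gene followed that share. But single oligodendrocyte genes changed by -0.80 to -0.0058 and cholesterol genes by -0.94 to -0.43, ranges that overlap. Astrocyte markers differed among themselves, with 6 lower and 1 higher adjusted over the list alone. These tests therefore do not exclude a lower share of either cell type. The cholesterol list's median of -0.71 lay at percentile 0 of 10000 matched random lists, which argues against a brightness trend as the only cause. Of the matched medians 2.5% lay below -0.35 and as many above 0.11, so such a trend may account for part of the fall. These lists too were drawn from all genes, so the range alone does not show such a trend. The hypothesis that sterol synthesis was turned down within cells goes with these values but was not tested. A lower share of oligodendrocytes, astrocytes or other sterol-making cells and the effect of the injection itself stay open.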
